A study of Mus musculus with 5 samples.

How the data were processed

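Polyadenylated RNA of 5 purified cell types of the mouse testis was sequenced, with 1 library per cell type, so no group has a replicate. The cell types were Sertoli cells, the somatic cells of the seminiferous tubule that nurse the germ cells, and 4 successive germ cell stages: spermatogonia, spermatocytes, spermatids and spermatozoa. All came from male C57BL/6 mice. Sertoli cells came from mice aged 3 weeks, spermatogonia from mice aged 6 days and the other 3 cell types from mice aged 11 weeks, so that age and cell type cannot be separated in any comparison with the first 2 libraries. How the cells were purified is not given in the sources used here. Per the labels' protocols, the libraries kept the strand, were read from a single end for 76 cycles, took 3 lanes each on a Genome Analyzer IIx and gave a mean of about 114 M reads per sample.

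The deposited unit is FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene, made by the authors, with a lower and an upper confidence bound and a status for each value per the file headers. TopHat 1.4.0, Bowtie 0.12.5, Cufflinks 2.0.0 and the mm9 build are named per the submitters' processing notes. The release of the gene annotation and the strand setting used in counting are not given in the sources used here, so overlapping and antisense genes are uncertain. No scaling between libraries is recorded. The files held 36810 Ensembl gene IDs in any library and 36809 in all 5, and the latter were analysed. The FPKM of 12 IDs listed on 2 loci were summed. Coordinates are those of the files, on mm9 and counted from 1. A GENCODE M21 annotation of a later build (GRCm38) served only to attach symbols and gene classes by ID, and gave a symbol to 31837 IDs (86.5%). Classes were protein-coding (20163), pseudogene (4757), small or structural RNA (3657), long non-coding (3009), other (270) and not in that annotation (4953).

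Depth was read from the bounds, since the upper bound of a Cufflinks value lies above it by 2 times the value divided by the square root of the fragment number. Among values with fewer than 20 implied fragments, between 61.1% and 61.9% per library were whole numbers within 0.02, and the ratio of fragments at a given FPKM gave a depth relative to spermatocytes of 1.33 in Sertoli cells, 0.973 in spermatogonia, 0.919 in spermatids and 0.983 in spermatozoa. An FPKM near 1 rested on a median of 178 fragments in Sertoli cells and between 84.1 and 93.8 in the other 4 libraries. At FPKM 10 or more the median distance from a value to its upper bound was between 3.56% of the value in Sertoli cells and 6.25% in spermatozoa. These bounds cover read assignment and counting only, not the spread between animals or preparations. Values marked FAIL numbered between 284 and 456 per library and those marked LOWDATA between 572 and 1031, and such a status is given beside a named gene.

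Genes with a span under 300 bp (5788 IDs) carried between 43.1% and 76.5% of the FPKM sum of a library, because the length that enters an FPKM becomes very small for a short gene. A single fragment gave Mir1945 and Snord60 an FPKM of 745 each in spermatocytes, and Snord80 stood at 96529 in spermatogonia on 75.2 fragments. Values of such genes are not read as abundance, but they enter the sums behind the rescaling to a common FPKM sum and largely set its factors.

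A gene counted as detected at FPKM 1 or more. Shares of genes carry exact (Clopper-Pearson) 95% intervals, which describe the gene models of one library and cover no spread between animals. The 4 comparisons set each stage against the one before it, with Sertoli cells before spermatogonia, on the scale log2((FPKM + 1)/(FPKM + 1)), which understates the change of low genes. A gene was called higher or lower at 2 or more on that scale, which is 4-fold. A median over expressed genes takes genes at FPKM 1 or more in either library. With 1 library per group no test between groups and no p-value was possible. The pool of transcripts was described by the Shannon effective number of genes and the share of the FPKM sum held by the highest genes. Specific genes had a tau index of 0.9 or more over the 5 libraries on log2(FPKM + 1), with FPKM 5 or more in the highest library. For each of 30 gene lists, the members past the 4-fold call, the median log2 ratio and its percentile among 10000 random lists of the same size were computed, the random lists being matched on mean expression in 20 bins. The percentile describes these 2 libraries only, and for the olfactory receptors it comes from ties at 0.

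The lists, the 15 pairs of germ-cell copies and their parent genes, the thresholds and the rule for named genes were chosen before the data were examined. The lists are markers of Sertoli cells, spermatogonia, spermatocytes, round spermatids, elongating spermatids and sperm, Leydig cells, peritubular myoid cells, macrophages, endothelial cells, erythroid cells, fibroblasts and epididymal epithelium, and genes of meiotic recombination and synapsis, the piRNA pathway, sperm chromatin packaging, acrosome and fertilisation, the sperm flagellum, testis-specific and somatic energy metabolism, the mitotic cell cycle, cytosolic ribosomal proteins, the mitochondrial genome, DNA methylation, retinoic acid signalling, blood-testis barrier junctions, the basement membrane, germ-cell transcription regulators, germ-cell RNA-binding proteins, chaperones and olfactory receptors. The rule took, per comparison, the 10 genes with the largest and the 10 with the smallest log2 ratio among genes with a symbol and FPKM 10 or more in one library; per library, the 10 with the highest FPKM and the 5 highest specific genes; and 2 to 4 members of each list and the pairs. Of the 80 places in the comparisons, 49 went to genes under 300 bp and 52 to genes listed at 0 in one library, so the same rule was also run among genes of 300 bp or more, a choice made after the values were seen. Where 5 or fewer members of a list passed 4-fold, further ones were named after their values were seen. Rhox5, Pou5f2, Hbb-b2 and Ldhal6b were not analysed here, and single values of some list members are not reported here.

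Alternatives set before the data were examined were other detection limits, pseudocounts of 0.1 and 5, rescaling of the 5 libraries to a common FPKM sum, scaling by the median ratio to the gene-wise geometric mean, a minimum FPKM of 5, calls with bounds apart, protein-coding genes alone for detection and the pool, other limits of tau, and leaving out the spermatozoa library for tau. Chosen after the values were seen were the 300 bp limit, the status and 10-fragment settings, protein-coding genes alone for the other results, the other settings for the detection of protein-coding genes, and genes under FPKM 1 in Sertoli cells. The largest factor that either rescaling put between 2 adjacent libraries was 1.72 on the log2 scale, which is below the call, so no 4-fold call changes direction under either. Leaving out a library is not possible in a comparison of 2. The calls, the tau index and the list percentile were tested on simulated data made from the spermatocyte library. Changed genes were drawn only from those at FPKM 10 or more, with at least 50 implied fragments and a span of 300 bp or more. Recovery of low or short genes was therefore not tested. The simulated libraries were Poisson draws around the implied fragments of that 1 library. They held counting noise only, with no spread between animals, preparations or purity. Of the changed genes, 50 of 50 raised 8-fold and 50 of 50 lowered 8-fold were called, and none of the 2-fold changes was. As the call is 4-fold, these outcomes were largely fixed by construction. Among all 36809 genes, 135 unchanged ones were called, which is a floor from counting noise and not a rate of false calls between these libraries. In 5 simulated libraries the tau limit found 200 of 200 genes placed in 1 library and also took 44 unchanged genes. The placed genes had no expression in the other libraries, so their recovery was fixed by construction. The median of an unchanged list of 20 genes lay at percentile 72.9, and at percentile 100 when raised by 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.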

Results

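The transcriptomes of Sertoli cells, spermatogonia, spermatocytes, spermatids and spermatozoa of C57BL/6 mice were set side by side to follow gene expression along male germ cell development, against the somatic cells that nurse the germ cells. Each cell type had 1 library of polyadenylated RNA, so none of the differences given here has a replicate check. Values are FPKM per gene, with the confidence bounds that came with them in the files, and cover 36809 Ensembl genes on mm9. Relative to the spermatocyte library, depth was 1.33 in Sertoli cells, 0.973 in spermatogonia, 0.919 in spermatids and 0.983 in spermatozoa.

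Spermatogonia had the most protein-coding genes at FPKM 1 or more, 12119 of 20163 (60.1%, exact 95% interval 59.4 to 60.8), and spermatids the fewest, 10036 (49.8%, 49.1 to 50.5). Sertoli cells had 10504 (52.1%, 51.4 to 52.8), spermatocytes 10461 (51.9%, 51.2 to 52.6) and spermatozoa 10174 (50.5%, 49.8 to 51.2). Above FPKM 0 spermatids had more protein-coding genes than spermatogonia, 17510 against 17482. Long non-coding RNA genes went another way: 765 of 3009 (25.4%, 23.9 to 27.0) were detected in spermatids and 640 (21.3%, 19.8 to 22.8) in spermatocytes, against 199 in Sertoli cells, 193 in spermatogonia and 286 in spermatozoa. Genes absent from the later annotation were likewise detected most often in spermatids (1132) and spermatocytes (988), and least often in Sertoli cells (591). Pseudogenes varied less, between 1487 in spermatozoa and 1739 in spermatocytes. Of all classes together, 8249 genes were detected in all 5 libraries and 16663 in none. Spermatocytes or spermatids, and no other library, had 1664 protein-coding and 649 long non-coding genes at FPKM 1 or more, while 724 protein-coding genes were detected in spermatogonia alone. The endothelial, erythroid, fibroblast, peritubular myoid and Sertoli lists, a set chosen after the results were seen, had 43 measured members. Of these, 37 (86.0%) were detected in the spermatogonia library, against 25 in Sertoli cells, 13 in spermatocytes, 15 in spermatids and 8 in spermatozoa. For the lists left out, counts follow in the order Sertoli cells, spermatogonia, spermatocytes, spermatids, spermatozoa. Of 10 macrophage members 9, 9, 2, 4 and 9 were detected, of 8 Leydig members 4, 5, 8, 1 and 0, and of 12 epididymal members 0, 2, 1, 1 and 4.

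**Figure D1:**
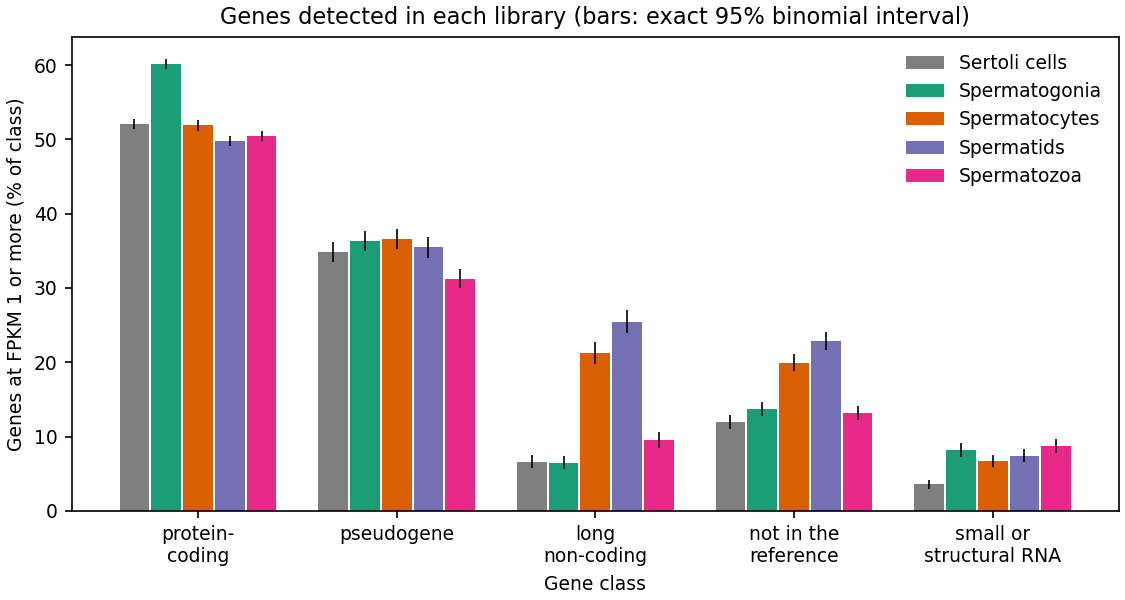
Share of genes at FPKM 1 or more, in percent of each gene class, for the 5 libraries (1 per cell type), with exact 95% binomial intervals as lines. Protein-coding genes peak in spermatogonia at 60.1% and long non-coding genes in spermatids at 25.4%.

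The most abundant protein-coding transcripts changed along the series. The highest was mt-Co2, a mitochondrially encoded subunit of cytochrome c oxidase, in Sertoli cells and spermatozoa, the translation factor Eef1a1 in spermatogonia, the germ-cell lactate dehydrogenase Ldhc in spermatocytes and the transition protein Tnp1 in spermatids. The mitochondrial genome held 29.6% of the protein-coding FPKM sum in spermatozoa and 0.973% in spermatids, with 5.64% in Sertoli cells, 3.76% in spermatogonia and 2.83% in spermatocytes. The 10 highest protein-coding genes took 32.6% of that sum in spermatozoa and 7.13% in spermatogonia. The effective number of protein-coding genes was 1674 in Sertoli cells, 3423 in spermatogonia, 2427 in spermatocytes, 2039 in spermatids and 785 in spermatozoa, and without the mitochondrial genes it was 2234 in spermatozoa, where Akr1b7 then came first. Over all classes, where values of short genes are not read as abundance, genes under 300 bp held between 43.1% of the FPKM sum in spermatocytes and 76.5% in spermatids. The highest gene took 57.9% of the sum in Sertoli cells, 10.3% in spermatogonia, 15.2% in spermatocytes, 6.29% in spermatids and 9.11% in spermatozoa.

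All 7 endothelial markers and 12 of 20 spermatogonia markers were higher in spermatogonia than in Sertoli cells, and 3 of 5 peritubular myoid markers were lower. Krt8 (ENSMUSG00000049382, chromosome 15, 101827142 to 101834773), an epithelial keratin, rose from 0.0670 (bounds 0.0283 to 0.106) to 786 (781 to 791), by 9.53 on the log2 scale. The chemokine Cxcl14 (ENSMUSG00000021508, chromosome 13, 56390008 to 56397912) was 189-fold lower, at 413 (409 to 416) in Sertoli cells and 2.18 (1.88 to 2.48) in spermatogonia, and the calcium-binding protein S100a4 (ENSMUSG00000001020, chromosome 3, 90407692 to 90409967) was 107-fold lower. Of 36809 genes, 1747 were at least 4-fold higher in spermatogonia and 611 lower.

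Among the spermatogonia markers, 12 of 20 rose and none fell, with a median log2 ratio of 2.42, at percentile 100 of the random lists. The receptor genes Ret (0.0518 to 18.8) and Gfra1 (0.0955 to 17.2), both of the GDNF pathway of spermatogonial stem cells, rose by 4.23 and 4.05, and Kit, Sall4 and Stra8 were listed at 0 in Sertoli cells and stood at 8.48, 5.88 and 8.02 in spermatogonia, Stra8 with a FAIL status. Piwi-interacting RNA (piRNA) genes, which silence transposons in germ cells, rose for 9 of 18, with Mael from 0.0467 to 18.5 and Ddx4 from 0.449 to 21.0. Of the meiotic genes 10 of 32 rose, among them Sycp1 (0.0851 to 9.68) and Smc1b (0.168 to 13.5), and of the spermatocyte markers 4 of 14 (Sycp1, Sycp3, Syce1 and Tex101). Genes of DNA methylation rose for 4 of 8, including Uhrf1 (0.607 to 31.5) and the maintenance enzyme Dnmt1 (3.41 to 34.3). Mitotic genes rose for 7 of 24, Mcm7 from 11.7 to 76.5, and Rrm2 fell. Germ-cell transcription regulators rose for 3 of 12 (Taf7l, Sohlh1 and Dmrt1), with Tcfl5, of LOWDATA status in Sertoli cells, lower, and the RNA-binding proteins rose for 2 of 13, Dazl from 0.0167 to 21.5 and Ddx25 from 0.225 to 5.13. Retinoic acid genes went both ways, with 4 of 17 higher and 2 lower, with Aldh1a1 from 1301 to 136. Of the genes of later stages, 3 of 33 flagellum genes (Tekt1, Ccdc39 and Ccdc40) and the energy isoform Slc25a31 rose, and Hist1h2ba of the chromatin list fell, while no round spermatid, elongating spermatid or acrosome gene passed 4-fold.

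The Sertoli markers did not separate these libraries: 4 of 19 rose, 1 fell and the median log2 ratio was 0.14, which became -0.13 under median-ratio scaling, at percentile 53.0 of the random lists as deposited. Amh, the anti-Müllerian hormone of immature Sertoli cells, stood at 0.674 in Sertoli cells and 39.5 in spermatogonia, and Sox9 at 8.28 and 71.2, while the iron carrier Trf fell from 107 to 16.1. All 7 endothelial markers rose, Pecam1 from 0.210 to 53.1 (51.6 to 54.6) and Cdh5 from 0.859 to 38.3. The globin genes Hba-a1 and Hbb-bs were listed at 0 in Sertoli cells and at 159 and 196 in spermatogonia, and 3 of 6 erythroid markers rose. The epithelial genes Krt18 (8.47 to 1220), Krt19 (0.163 to 376) and Cdh1 (0.0592 to 172) rose beside these markers. Blood-testis barrier junction genes rose for 6 of 14, Ocln from 0.172 to 32.8 and Gja1 from 21.3 to 153. Fibroblast markers were high in both libraries, with Lum alone of 6 higher, and their median of 0.05 became -0.23 under median-ratio scaling. Contractile myoid markers fell for 3 of 5, Acta2 from 1529 to 185 and Tagln, with a FAIL status in Sertoli cells, from 2625 to 173, and macrophage markers for 4 of 10, with Lyz2 from 112 to 4.87. Of the Leydig markers Hsd17b3 rose and Cyp11a1 fell, of the basement membrane genes Lama5 rose and Lama1 fell, and 1 of 12 epididymal markers, Crisp1, rose from a listed 0 to 46.8. Somatic energy genes fell for 2 of 12, Eno1 and Slc25a4. Of 81 ribosomal protein genes the germ-cell copies Rpl10l and Rpl39l rose and Rpl22 and Rps27l fell, and no mitochondrial gene or chaperone passed 4-fold.

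Rescaling the libraries to a common FPKM sum gave 2322 higher and 133 lower, or 94.6% higher against 74.1% as deposited, and median-ratio scaling gave 59.6%. The median over expressed genes was 0.38 as deposited, 0.90 under the rescaling to a common sum and 0.13 under median-ratio scaling. Genes under 300 bp, whose values are not read as abundance, held 75.2% of the FPKM sum in Sertoli cells and 65.5% in spermatogonia, so that values at a common sum, here and in the later comparisons, depend largely on them.

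Spermatocytes, the cells in meiosis, had higher levels than spermatogonia of most genes of the spermatocyte, piRNA, acrosome and flagellum lists, and most Sertoli, endothelial, fibroblast and myoid markers were lower. Ldhc (ENSMUSG00000030851, chromosome 7, 54116573 to 54133512) rose from 0.430 (0.132 to 0.728) in spermatogonia to 7123 (7087 to 7160) in spermatocytes, by 12.28. The sperm protein Crisp2 rose from 0.0520 to 1848, and Cmtm2a was listed at 0 in spermatogonia and at 3494 in spermatocytes. Krt18 (ENSMUSG00000023043, chromosome 15, 101858647 to 101862457) fell from 1220 (1212 to 1227) to 0.13 (0.0577 to 0.202), a log2 ratio of -10.08. In all, 3292 genes were at least 4-fold higher and 3990 lower.

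Of the spermatocyte markers 12 of 14 rose, with a median of 4.94 (percentile 100), and of the meiotic genes 18 of 32. The synaptonemal complex gene Syce1 rose 79.4-fold, from 10.4 to 822, Sycp3 rose from 8.27 to 204, and Spo11, whose product makes the meiotic double-strand breaks, from 0.195 to 56.1. Of the piRNA genes 13 of 18 rose, among them Mael (18.5 to 542) and Piwil1 (ENSMUSG00000029423), which went from 0.245 to 129 (128 to 131). Transcripts named for later stages were already high in the spermatocyte library: 14 of 14 round spermatid markers and 12 of 12 elongating spermatid markers rose. The elongating markers had a median FPKM of 193 in spermatocytes and 1365 in spermatids. RNA carried over from spermatids may be a source of part of these values, as set out under the other observations. Acrosome genes rose for 25 of 27, flagellum genes for 33 of 33 and sperm chromatin genes for 10 of 12. Adam3 stood at 0.0464 and 702, Ropn1l at 3.81 and 2968, and Tnp1 at 0.699 and 1221. Transcription regulators rose for 7 of 12, with Rfx2 from 1.33 to 70.0 and Dmrtb1 from 0.494 to 345, and fell for 2, Dmrt1 and Sohlh1. The RNA-binding proteins rose for 6 of 13, with Ybx2 from 0.968 to 1003, and Celf1 fell.

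Energy genes exchanged isoforms, with 9 of 11 testis-specific isoforms higher and 7 of 12 somatic counterparts lower, while Ldha rose. Pgk2 went from 0.0353 to 276 and Pgk1 from 59.6 to 1.91. Chaperones split likewise: 5 of 11 rose, led by Dnajb3 (2.52 to 464) and Hspa2 (8.94 to 677), and 4 fell, among them Hsp90ab1 (2576 to 239). Mitotic genes rose for 2 of 24, Ccnb2 and Plk1, and fell for 7, with the cyclin Ccnd1 from 49.0 to 0.207. Spermatogonia markers fell for 10 of 20, Ret from 18.8 to 0.0365. DNA methylation genes fell for 3 of 8, the methyltransferase Dnmt3a from 13.9 to 0.371, and retinoic acid genes for 6 of 17. Ribosomal protein genes fell for 12 of 81, Rpl10l and Rpl39l rose, and of the 13 mitochondrial genes mt-Nd6 fell.

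Several somatic lists fell. Of the Sertoli markers 14 of 19 fell, with Vim from 1259 to 11.8, of the endothelial 7 of 7, of the fibroblast 6 of 6, of the myoid 5 of 5 and of the erythroid 3 of 6. Junction genes fell for 11 of 14, and basement membrane genes for 8 of 11, including Col4a2 from 186 to 0.360. The actin-binding Tagln2 fell from 1034 to 1.83. No macrophage marker passed 4-fold. Of the Leydig markers 3 of 8 were higher and none lower. Cyp17a1 rose from 1.80 to 107, Hsd3b6 was listed at 0 and then at 34.6, and Insl3, with a FAIL status, rose from 0.344 to 485. Whether these values come from other cell types in the spermatocyte library was not tested. Of the epididymal markers Rnase10 rose and Crisp1 fell. The share of higher calls was 45.2% as deposited and 60.5% (3777 higher, 2471 lower) when the libraries were rescaled to a common sum. The median over expressed genes was -0.46, against 0.08 under that rescaling and -0.21 under median-ratio scaling.

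Spermatids, the haploid cells that build the acrosome and tail and compact the nucleus, had higher levels than spermatocytes of all 14 round spermatid markers and 11 of 12 elongating spermatid markers. Prm2 (ENSMUSG00000038015, chromosome 16, 10791476 to 10792198), a protamine that replaces histones in sperm, rose 11.3-fold, from 718 (709 to 728) to 8120 (8088 to 8152). Tnp1 (ENSMUSG00000026182, chromosome 1, 73061657 to 73062473) rose 9.41-fold, from 1221 (1205 to 1238) to 11494 (11440 to 11547). The steroidogenic enzyme Cyp17a1 (ENSMUSG00000003555, chromosome 19, 46741655 to 46747464) was 202-fold lower, at 107 (105 to 109) and 0.531 (0.400 to 0.661). Altogether 1532 genes were at least 4-fold higher and 581 lower.

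All 14 round spermatid markers rose, with a median of 2.40 (percentile 100), and 11 of 12 elongating spermatid markers, with a median of 2.92. Gapdhs, the sperm glycolytic enzyme, went from 131 to 1032, and Akap4, a scaffold of the tail's fibrous sheath, from 74.3 to 594. Acrosome genes rose for 14 of 27, with Izumo1, the sperm ligand for the egg, at 15.5 and 77.0, and Gopc fell. Sperm chromatin genes rose for 8 of 12, with Chd5 from 7.24 to 43.8. Flagellum genes rose for 11 of 33, such as Ropn1 (71.8 to 417) and Akap3 (44.1 to 258), while Tekt1 (344 and 430) did not pass 4-fold. The list's median of 0.48 became -0.87 when the libraries were rescaled to a common sum. Testis-specific energy isoforms rose for 3 of 11, among them Aldoart2 (26.1 to 156), and the chaperone Hspa1l rose from 31.6 to 265.

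The piRNA genes fell for 4 of 18, namely Piwil1 (14.1-fold, 129 to 9.15), Tdrd5 (63.3 to 3.91), Tdrd1 (37.6 to 4.55) and Pld6 (37.4 to 4.44). The median log2 ratio of that list was -1.16 (percentile 0.01). Of the meiotic genes 2 of 32 rose, Rec8 and M1ap, and Mlh3 fell. Of the spermatocyte markers, Piwil1 fell and 13 of 14 stayed within 4-fold, but the list's median log2 ratio was -1.23 (percentile 0.01). Its median FPKM was 97.5 in spermatocytes and 26.3 in spermatids. Mitotic genes fell for 2 of 24, Aurkb and Cdk1. The DNA methylation gene Dnmt1 fell from 11.8 to 1.61, the retinoic acid gene Aldh1a1 from 92.1 to 6.64, and the spermatogonia marker Id4 from 18.7 to 2.18. Leydig markers fell for 7 of 8 (median -4.85, percentile 0), with Star at 68.9 and 0.891 and Cyp11a1 at 36.1 and 0.198. All 8 were at FPKM 1 or more in the spermatocyte library, and RNA from other cell types there was not tested. Among the other genes with the lowest ratios were Lcn2 (285 to 1.43), Agt (82.7 to 0.637) and Ptgds (116 to 2.06). No gene of the Sertoli, myoid, macrophage, endothelial, erythroid, fibroblast, epididymal, ribosomal, mitochondrial, somatic energy, junction, basement membrane, transcription regulator or RNA-binding lists passed 4-fold.

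The share of higher calls was 72.5% as deposited, 87.1% under median-ratio scaling (2188 higher, 324 lower) and 7.0% with the libraries rescaled to a common sum (214 higher, 2845 lower), with medians over expressed genes of -0.30, 0.13 and -1.17. The median of the round spermatid markers was 1.04 and that of the elongating markers 1.56 under the rescaling to a common sum. That rescaling rests on sums of which genes under 300 bp held 43.1% in spermatocytes and 76.5% in spermatids, and values of such genes are not read as abundance.

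Most genes of the spermiogenic lists were lower in spermatozoa than in spermatids, and all 13 mitochondrial genes and 4 of 12 epididymal markers were higher. Akr1b7 (ENSMUSG00000052131, chromosome 6, 34362334 to 34373142), an aldo-keto reductase, rose from 0.0447 (0 to 0.0911) in spermatids to 14223 (14198 to 14248) in spermatozoa, by 13.73. Meig1 (ENSMUSG00000026650, chromosome 2, 3326315 to 3339920), needed to build the sperm tail, was 827-fold lower, at 6447 (6399 to 6495) and 7.80 (6.76 to 8.84). The mitochondrial mt-Co2 (ENSMUSG00000064354, MT, 7013 to 7696) was 16.9-fold higher, at 1901 (1887 to 1915) and 32201 (32144 to 32258). At least 4-fold higher were 2758 genes, and 4974 were lower.

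All 13 protein-coding mitochondrial genes rose, with a median of 4.48 (percentile 100). The spermiogenic lists fell nearly whole: 14 of 14 round spermatid markers, 10 of 12 elongating spermatid markers, 26 of 27 acrosome, 31 of 33 flagellum, 10 of 12 chromatin and 11 of 11 testis-specific energy genes. Prm1 fell from 1202 to 6.78 and Prm2 from 8120 to 237, whereas Odf1, of the outer dense fibres (1527 and 619), and Smcp, of the mitochondrial capsule (2333 and 1057), did not pass 4-fold. In the acrosome list Gopc rose. Genes of earlier stages fell too, with 13 of 14 spermatocyte markers, 19 of 32 meiotic, 16 of 18 piRNA, 7 of 12 transcription regulator and 8 of 13 RNA-binding genes lower, Ddx4 going from 163 to 0.181 and Syce1 from 636 to 1.41. The RNA-binding genes Celf1 and Cpeb1 rose.

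Part of the epididymal list rose. Crisp1 (ENSMUSG00000025431, chromosome 17, 40430707 to 40456156), secreted by the epididymis, rose from 0.0642 to 6315 (6299 to 6331), and 4 of 12 epididymal markers rose, Adam7, Lcn5 and Lcn12 reaching 26.8, 3.45 and 7.90. Gpx5 (0.251), Lcn8 (0.0820) and Lcn9 (listed at 0) stayed low in spermatozoa. The defensin Defb43 and the protease inhibitor Spink8 were listed at 0 in spermatids and at 1181 and 2135 in spermatozoa, and Ptgs2 rose from 0.0361 to 1986. The keratin genes Krt19 and Krt18 rose, to 479 and from 0.575 to 117, while Krt7 was listed at 0 in spermatids and at 0.944 in spermatozoa. Macrophage markers rose for 2 of 10, Lyz2 and Tyrobp, and erythroid markers for 3 of 6, Hba-a1 to 10.3. Clu, in the Sertoli list, rose from 47.8 to 2516, and so did Trf, while 6 of 19 Sertoli markers fell. Junction genes rose for 5 of 14, with Cldn3 from 0.464 to 22.3, and fell for 4, among them Cdh2 from 9.76 to 0.0115. Basement membrane genes rose for 3 of 11 (Lama1, Lamb2 and Lamc1), somatic energy genes for 5 of 12, Pgk1 among them, with Ldha lower, and DNA methylation genes for 3 of 8 (Dnmt1, Tet2 and Tet3), with Uhrf1 and Dnmt3l, the latter of FAIL status in spermatids, lower. Chaperones rose for 3 of 11 (Hspa8, Hsp90ab1 and Hspd1) and fell for 6, mitotic genes rose for 1 of 24, Ccnd1, and fell for 11, and of the retinoic acid genes Aldh1a1 and Rarg rose and Aldh1a2 and Stra8 fell. Ribosomal protein genes rose for 6 of 81 and fell for 7, and their median of -0.90 became 0.76 with the libraries rescaled to a common sum. Of the spermatogonia markers Etv5 rose and Stra8 and Uchl1 fell, of the fibroblast markers Dcn fell, and no Leydig, myoid or endothelial marker passed 4-fold. Olfactory receptors, 851 genes, were almost silent throughout, with none past 4-fold between spermatogonia and Sertoli cells, Olfr701 higher in spermatocytes and again in spermatids, and Olfr701 and Olfr112 lower in spermatozoa. The share of higher calls was 35.7% as deposited, and 65.0% (4661 higher, 2505 lower) with the libraries rescaled to a common sum, with medians over expressed genes of -0.55 and 0.77, and -0.30 under median-ratio scaling.

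**Figure D2:**
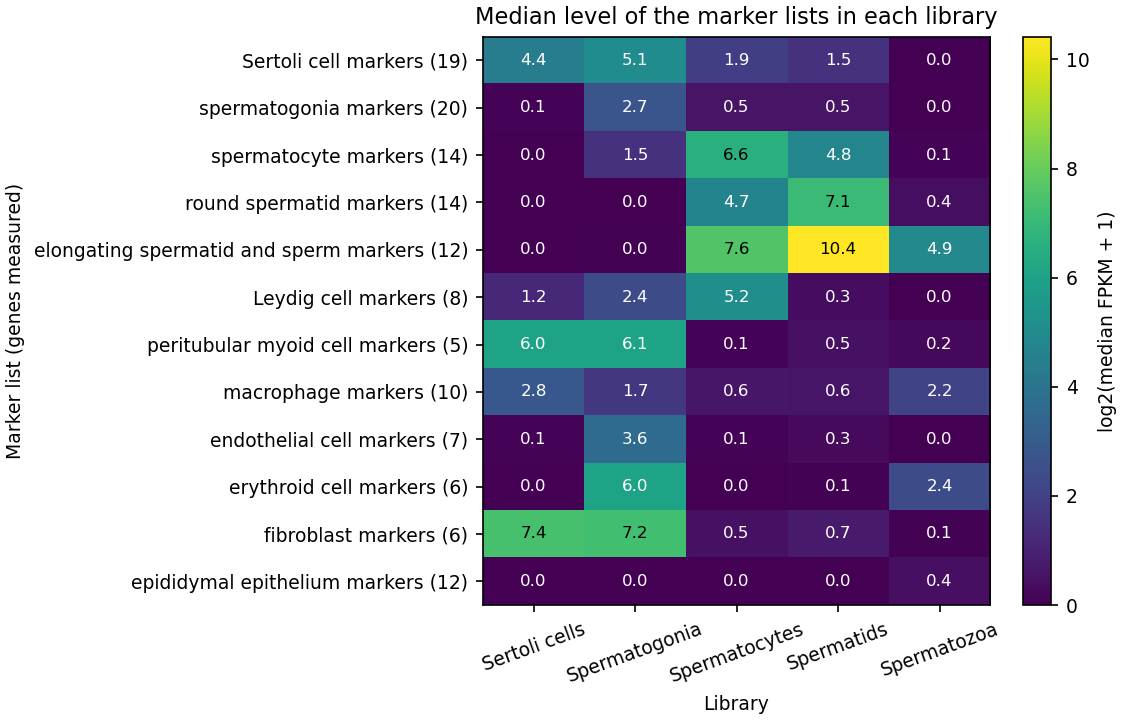
Median expression of 12 marker lists, as log2(median FPKM + 1) in colour, in the 5 libraries (1 per cell type). Round and elongating spermatid lists are high in the spermatocyte and spermatid libraries (the elongating list at a median FPKM of 193 and 1365). The endothelial list is high in the spermatogonia library (11.4) and the Leydig list in the spermatocyte library (35.4). A level describes the library, which may hold RNA of other cell types.

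X-linked genes, which are silenced during male meiosis, had a lower median ratio than autosomal genes from spermatogonia to spermatocytes and a higher one from spermatocytes to spermatids. Over expressed X genes the median log2 ratio was -1.19 (95% interval -1.28 to -1.08) from spermatogonia to spermatocytes, against -0.42 for the autosomes, and 1.17 (1.04 to 1.35) from spermatocytes to spermatids, against -0.34. Of 1059 expressed X genes, 335 (31.6%) fell at least 4-fold into spermatocytes, against 21.4% of autosomal genes, and 152 (14.4%) rose, against 18.4%. Into spermatids 236 of 855 (27.6%) rose, against 8.82%, and 11 (1.29%) fell, against 3.93%. The X share of the protein-coding FPKM sum was 4.95% in Sertoli cells, 3.10% in spermatogonia, 0.414% in spermatocytes, 1.66% in spermatids and 2.49% in spermatozoa. The 20 Y genes had medians of -2.37 into spermatocytes (12 expressed) and 1.46 into spermatids (14 expressed). Between spermatogonia and Sertoli cells the X median was 0.37 (0.23 to 0.50) and the autosomal one 0.38. From spermatids to spermatozoa the X median was -1.23 (-1.43 to -1.07), a difference of -0.73 from the autosomes, but among protein-coding genes alone the difference was 0.58. The intervals are over genes of a pair of libraries.

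**Figure D3:**
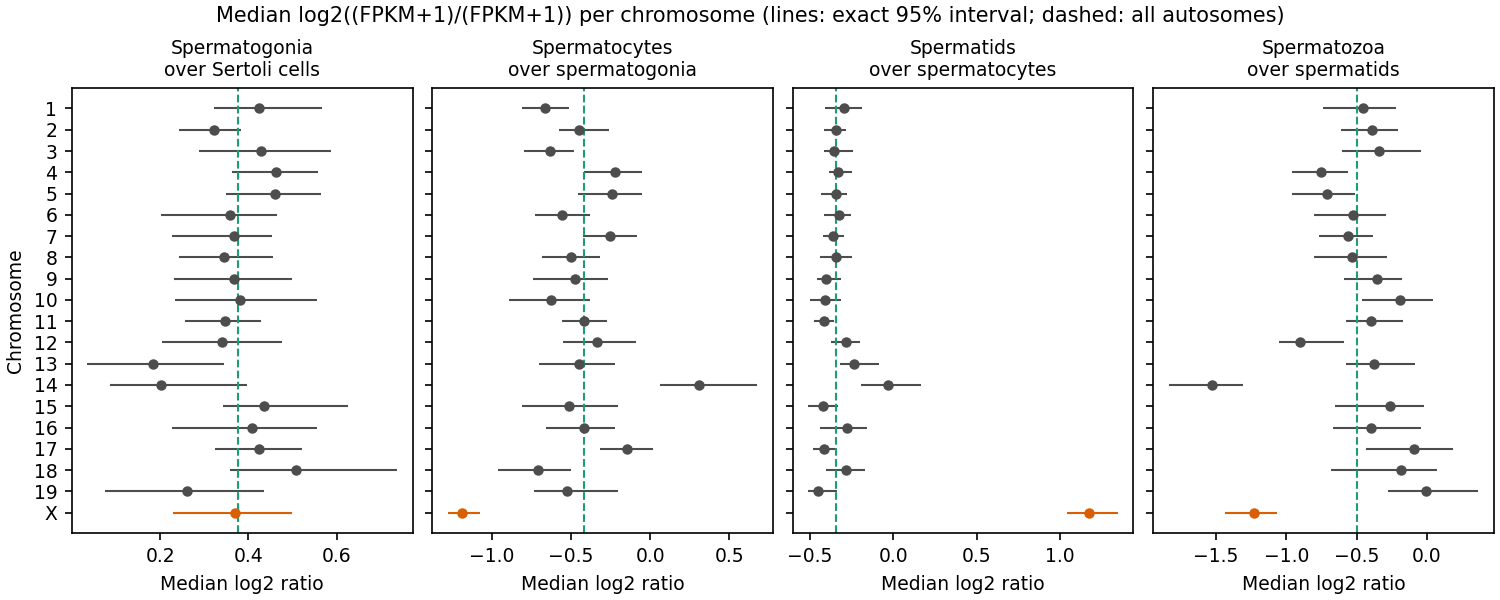
Median log2 ratio of expressed genes on chromosomes 1 to 19 and X in the 4 comparisons, with exact 95% intervals over genes as lines and the autosomal median dashed. The X lies at -1.19 in spermatocytes over spermatogonia and at 1.17 in spermatids over spermatocytes.

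Germ-cell copies of housekeeping genes exceeded most of their parent genes in spermatocytes and spermatids. Among 15 pairs, the copy exceeded the parent in 0 in Sertoli cells, 0 in spermatogonia, 13 in spermatocytes, 13 in spermatids and 2 in spermatozoa. The median share of the copy in the pair's summed FPKM was 0.0391%, 4.10%, 96.2%, 95.9% and 5.28%, in the same order. In spermatocytes the autosomal Pdha2 stood at 69.0 and X-linked Pdha1 at 0.952, Rpl10l at 505 and X-linked Rpl10 at 27.5, and Cetn1 at 768 and X-linked Cetn2 at 3.61. The same held for parents on autosomes, with Cox8c at 1476 and Cox8a at 7.84. Cstf2t and Pabpc2 stayed below their parents in spermatocytes and spermatids. In spermatozoa the copies Pgk2 (58.9%) and Gapdhs (56.3%) exceeded their parents. Reads shared between a copy and its parent are a limit of these shares.

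**Figure D4:**
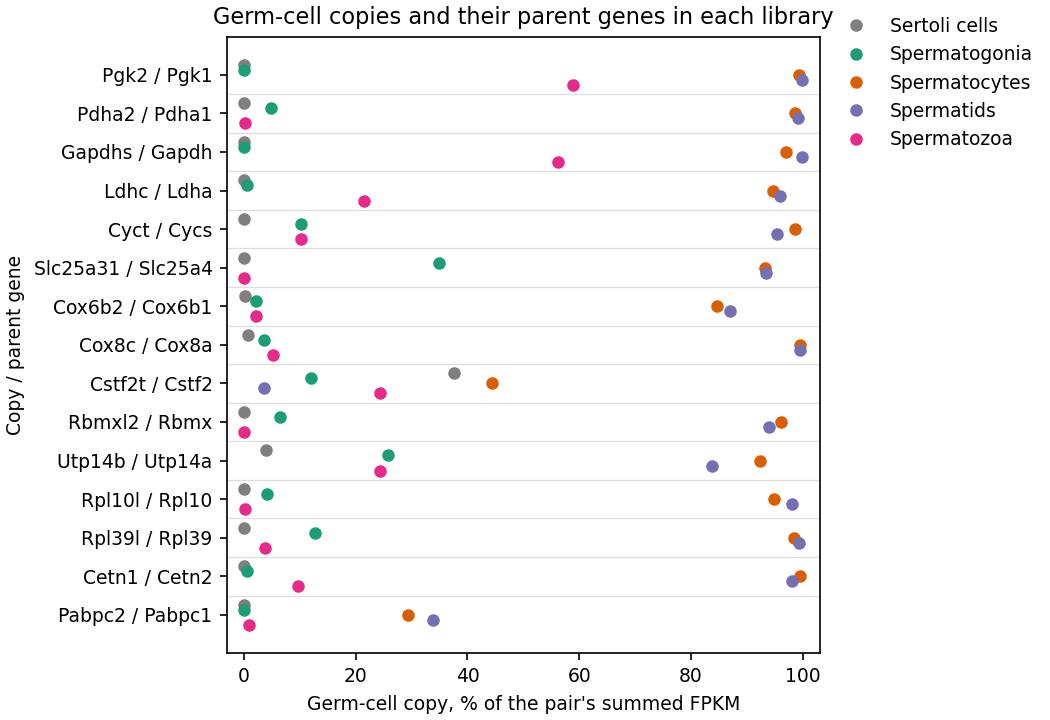
Share of the germ-cell copy in the summed FPKM of copy and parent, in percent, for 15 pairs in the 5 libraries (1 per cell type). The median share is 96.2% in spermatocytes and 95.9% in spermatids, and 5.28% or less in the other 3 libraries.

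Genes past the tau limit for 1 library numbered 746, with 66 in Sertoli cells, 203 in spermatogonia, 78 in spermatocytes, 203 in spermatids and 196 in spermatozoa. In 5 simulated libraries made from the spermatocyte one, which differed by counting noise only, 44 unchanged genes passed it. Of the 746 genes, 366 were protein-coding, 130 of them in spermatogonia and 111 in spermatozoa, and 32 of the spermatid genes were long non-coding. The Sertoli cell library was marked by Cxcl14, the steroid-metabolising Akr1c14 (55.3) and the smooth-muscle gene Lmod1 (54.6). In that library the myoid and fibroblast lists had median FPKM of 64.7 and 167, against 20.1 for the Sertoli list. RNA from other cell types in it was not tested. The spermatogonia library was marked by Krt7 (161), the imprinted RNA H19 (122), elastin Eln (114), Krt20 (108) and Gpc3 (95.6). In that library the fibroblast list had a median FPKM of 151 and the spermatogonia list one of 5.64. These genes may therefore come from other cell types, which was not tested. The genes of 300 bp or more in the spermatocyte library included the Leydig markers Insl3, Cyp17a1 and Hsd3b6 together with Bhmt (47.5). All 8 Leydig markers were at FPKM 1 or more in that library, and RNA from other cell types there was not tested. The spermatid library had Defb33 (21.6) and E330034G19Rik (19.8), and the spermatozoa library Akr1b7, Serpina1f (1819), Defb43 (1181) and Defb42 (640). RNA from epithelial cells of the male tract, considered under the other observations, was not separated from these genes of the spermatozoa library.

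Across genes, which are not independent replicates, spermatocytes and spermatids were the most alike (Spearman 0.928, Pearson 0.912 on the log2 scale), followed by Sertoli cells and spermatogonia (0.891 and 0.899). The spermatozoa library was closer to spermatogonia (0.844 and 0.823) and Sertoli cells (0.819 and 0.780) than to spermatocytes (0.770 and 0.657) or spermatids (0.724 and 0.597). Of 2735 protein-coding genes detected in spermatozoa and not in spermatids, 83.6% were also detected in spermatogonia. The share among all protein-coding genes was 60.1%, but that set includes genes detected in no library. It is therefore not a matched baseline, and the share among all genes detected in spermatozoa was not computed. No particular link to spermatogonia is drawn from these shares. Of 20 general epithelial genes, 19 were detected in spermatozoa, 20 in spermatogonia, 5 in spermatocytes and 4 in spermatids. How far RNA from other cell types sets these correlations was not tested. Over all genes the lowest values were those of Sertoli cells and spermatids (0.667 and 0.574). When only genes at FPKM 1 or more in one library were kept, the lowest Pearson value was that of spermatogonia and spermatids.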

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

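The 300 bp limit, the status and 10-fragment settings, protein-coding genes alone for calls, X and similarity, the other settings for protein-coding detection, and genes under FPKM 1 in Sertoli cells were chosen after the results were seen. Alternatives were set against the main results (detection, pool, calls, specific genes, X and Y, copies and similarity). Of their values, 163 were the same as reported, 99 moved and 1 reversed. Same meant within the 95% interval or 1.5 times, or a small absolute difference for correlations. Only the X and the correlations could be labelled reversed by these rules. Calls crossed from one majority to the other without that label. At a common sum the share of higher calls went from 45.2% to 60.5% in spermatocytes and from 72.5% to 7.0% in spermatids. In spermatozoa it went from 35.7% to 65.0%. Of the values for single lists, 282 were the same, 75 moved and 3 reversed. Where a value moved because a limit admits more or fewer genes, the construction shows the cause; for the others the cause was not tested. With 1 library per group no replicate could be left out, and no paired analysis was possible because no group has a second replicate. Depth limits low genes most. An FPKM near 1 rested on a median of 84.1 fragments in spermatocytes and 178 in Sertoli cells. These medians are over different genes in each library, so they do not reflect depth alone.

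In the order Sertoli cells, spermatogonia, spermatocytes, spermatids, spermatozoa, genes above FPKM 0 numbered 19830, 23666, 24382, 24708 and 22221, and genes at FPKM 10 or more 6439, 7833, 7302, 7036 and 5421. Protein-coding genes numbered 15092, 17482, 17363, 17510 and 16276 above FPKM 0 and 4871, 6053, 5439, 4966 and 4076 at FPKM 10 or more. The effective number of genes, which short RNAs pull down, was 1674, 3423, 2427, 2039 and 785 for protein-coding genes and 1606, 3105, 3059, 2787 and 1184 for genes of 300 bp or more. Specific genes numbered 206, 430, 238, 1152 and 334 at a tau of 0.8, and 136, 481, 163, 610 and 340 with FPKM 1 or more. With a pseudocount of 0.1 they were 24, 108, 47 and 75 in the first 4 libraries. In spermatids they were 127 among genes of 300 bp or more, 405 under median-ratio scaling and 118 with spermatozoa left out, and in spermatocytes 36 among genes of 300 bp or more.

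Calls in the order of the 4 comparisons, higher and lower, were as follows. A pseudocount of 0.1 gave 4065 and 1101, 4961 and 6547, 2708 and 1430, and 4781 higher in spermatozoa. A pseudocount of 5 gave 577 and 326, 1878 and 1757, 792 and 196, and 1006 and 3055. Rescaling to a common sum gave 133 lower in spermatogonia, 2471 lower in spermatocytes, 214 higher and 2845 lower in spermatids, and 4661 higher and 2505 lower in spermatozoa. Median-ratio scaling gave 324 lower in spermatids. Protein-coding genes alone gave 876 and 384 in spermatids and 3289 lower in spermatozoa. Genes under FPKM 1 in Sertoli cells gave 2180 and 645 in spermatocytes, 221 lower in spermatids, and 649 and 2885 in spermatozoa.

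The X minus the autosomes was 0 in spermatocytes, spermatids and spermatozoa with no expression filter, where genes below FPKM 1 in both libraries also entered. It was -1.34, 2.26 and -1.24 with a pseudocount of 0.1, and -0.88 and 1.35 in spermatocytes and spermatids under median-ratio scaling. Among protein-coding genes it was -1.29 and 1.73, and 0.58 in spermatozoa, which reversed; the cause was not tested. Under rescaling to a common sum the ribosomal list reversed to 0.38 in spermatogonia and 0.76 in spermatozoa, and the mitochondrial list to 0.18 in spermatogonia, since one factor moved every gene.

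Pearson correlations were lower when genes at FPKM 1 or more in one library were kept: Sertoli cells with spermatocytes 0.497, spermatids 0.362 and spermatozoa 0.674, spermatogonia with spermatocytes 0.470 and spermatids 0.349, spermatocytes with spermatozoa 0.467 and spermatids with spermatozoa 0.386. Among protein-coding genes they were 0.546 and 0.434 for Sertoli cells with spermatocytes and spermatids, 0.548 and 0.442 for spermatogonia with the same, 0.555 for spermatocytes with spermatozoa and 0.462 for spermatids with spermatozoa.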

Other observations

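The chromosome regions, and the tests of spermatocyte bounds, of ratios against the elongating list, of spermatid levels of the epididymal genes, of depth and of RNA from other cell types, and the settings for protein-coding detection and the 10-fragment setting, were chosen after the results were seen. Some chromosome regions held many genes that were higher in spermatocytes. Below 9 Mb on chromosome 14, 59 of 126 expressed genes were at least 4-fold higher in spermatocytes than in spermatogonia and 11 lower, with a median log2 ratio of 1.87, and between 42 and 45 Mb 36 of 50 were higher and 0 lower, with a median of 3.46. Elsewhere on the chromosome 109 of 578 were higher and 134 lower, with a median of -0.43. From spermatids to spermatozoa 109 of 136 and 67 of 77 genes of these regions were lower. Gm10376 stood at 88.0 in spermatocytes and 670 in spermatids, and Gm3486 at 58.0 and 414. Of the 124 genes detected in spermatocytes in the first region, 10 had a value that another gene there also had, and 0 of 49 in the second. Genes that share reads need not have equal values, so these counts do not exclude shared reads. Of the same genes, 59 of 124 and 16 of 49 are absent from the later annotation.

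Of 852 windows of 1 Mb with at least 8 expressed genes, 20 had a median of 2 or more between spermatogonia and spermatocytes. The highest, at 11 Mb on chromosome 5, had 11 of 11 genes higher and a median of 8.29, and included Gm6455 and 4933402N22Rik, both listed at 0 in spermatogonia and at 381 and 243 in spermatocytes. On the X, where the median of expressed genes was lower in spermatocytes, the window at 52 Mb had 9 of 9 genes higher and a median of 5.98, with Slxl1 at 0.187, 63.6 and 357 and Gm14622 at 0.0929, 22.1 and 125 in spermatogonia, spermatocytes and spermatids. The window at 10 Mb on chromosome 16, with the protamine genes and Tnp2, had 8 of 15 genes higher and a median of 3.96. Slxl1, Gm14622, Gm10376 and Gm3486 were each higher in spermatids than in spermatocytes. RNA carried over from spermatids may therefore add to the spermatocyte values of these windows and regions, which was not tested for them. Reads shared between near-identical copies are a further limit of such values.

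Spermatid genes were already high in the spermatocyte library. The set tested was 550 protein-coding genes at FPKM 50 or more in spermatids and under 1 in Sertoli cells and spermatogonia. Of these, 193 (35.1%, exact 95% interval 31.1 to 39.2) had a ratio of spermatocytes to spermatids at least 4 times the elongating list's median of 0.131. No scaling changes that comparison. The set was not limited to genes that start in spermatids: Ldhc, at 7123 in spermatocytes and 6114 in spermatids, met its limits. The result therefore argues against RNA carried over from spermatids in 1 ratio as the whole source for those 193 genes only. It does not bear on genes near the elongating list's ratio. Of the 550 genes, 0 (0%) lay below 0.05 of the spermatid value, the lowest ratio was 0.0844, and 290 (52.7%) lay between 0.1 and 0.2. The ratio was 0.0885 for Prm2, 0.106 for Tnp1 and at most 0.262 in the elongating list. Carried-over RNA may still be a source for part of the set. By 2 other tests it cannot be told apart from transcription in spermatocytes: 46.4% (255 genes) lay at 0.2 or more, between the limits of 5% and 50% set for that test, and 17.1% (94 genes) had a lower bound in spermatocytes above the upper bound in spermatids as deposited but 5.45% (3.71 to 7.70) under median-ratio scaling and 36.5% (32.5 to 40.7) with the libraries rescaled to a common sum, which short genes largely set, with bounds that cover read assignment and counting only. Early transcription of spermatid genes in spermatocytes, and carried spermatids of another mix of stages than the spermatid library, stay open and were not tested.

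Of the 12 epididymal markers, 4 were at FPKM 1 or more in the spermatozoa library, with Crisp1 at 6315. The 4 epididymal markers at FPKM 1 or more in spermatozoa, taken on that library alone, had a median FPKM of 0 in spermatids and a highest of 0.0642, which argues against their retention from cells like those of the spermatid library. RNA from epithelial cells of the male tract is a candidate source: of 20 general epithelial genes, 18 (90%) were at least 4-fold higher in spermatozoa than in spermatids, with Krt19 at 479 and Krt18 at 117. Values of Krt18 and Cldn3 had been seen before that list was written, 1 of its genes is in another list, and 20 of the 20 were detected in spermatogonia. RNA taken up by sperm from the epididymis stays open and was not tested.

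The spermatogonia library had the most protein-coding genes detected as deposited, under both rescalings, at FPKM 0.1 and 10 and at 10 implied fragments, while above FPKM 0 spermatids had more (17510 against 17482). Over all gene classes its lead was less stable: spermatids had more under median-ratio scaling (14503 against 14254), at FPKM 0.1 (19928 against 19668) and above 0 (24708 against 23666), and spermatocytes with the libraries rescaled to a common sum (13500 against 13455) and at 10 implied fragments (18380 against 18169). Its depth was 0.973 of the spermatocyte library while that of Sertoli cells, with fewer genes detected, was 1.33, which argues against greater depth. RNA from other cell types is a candidate explanation. Of the endothelial, erythroid, fibroblast, myoid and Sertoli lists, 37 of 43 members (86.0%) were detected there, with Hba-a1 at 159, Pecam1 at 53.1 and Amh at 39.5. The macrophage, Leydig and epididymal lists were left out of that set, with 9 of 10, 5 of 8 and 2 of 12 members detected. These lists did not single out spermatogonia. Macrophage members were detected as often in Sertoli cells and in spermatozoa (9 of 10 each), all 8 Leydig members in spermatocytes, and 4 of 12 epididymal members in spermatozoa. Broader transcription in spermatogonia themselves, and the age of 6 days, stay open and were not tested.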
